A study of Caenorhabditis elegans with 2 samples.

How the data were processed

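The series measured where CEH-6, a POU homeodomain transcription factor of Caenorhabditis elegans, sits on chromatin. Per the labels, the worms carried a transgene in which CEH-6 is joined to a Ty1, eGFP and 3xFLAG tag, together with a wild-type copy of unc-119 as transformation marker in an unc-119 mutant. Chromatin was fragmented by sonication and immunoprecipitated with an antibody against GFP. Both samples were late embryos of mixed sex with an age label of 3.3 hours, whose starting point is not stated, and the labels number them as biological replicates 1 and 2 of 1 group. No other genotype, stage or mock immunoprecipitation belongs to the design, so no comparison between groups of samples was possible.

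The authors deposited 4 lists of regions on assembly ce11. One list was called on each replicate and one on the reads of both replicates together. The last holds the peaks that passed the irreproducible discovery rate (IDR) procedure, which compares the ranks of regions between replicates. Each list was made against 1 control, per the text deposited with the files. The peak caller, the aligner and the filters on reads that map to several places are not given in the sources used here. The value of each region is the signal that the authors' caller gave it relative to that control, and its scale is not stated. It was used here only to describe and rank regions within a list. The deposited lists hold no read counts, so the depth of each sample is unknown. The relaxed lists of the replicates and of the pooled reads have 30000 regions each. The 741 IDR peaks had the same coordinates and signal as the 741 regions of highest signal in the pooled list. The IDR set thus equals a cut on pooled signal, and a single IDR peak need not be reproducible between the replicates.

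From here on the work was done on those lists. Background regions were the 29094 regions of the pooled list that overlap no IDR peak. They could have become peaks and were called on the same reads. Summits were placed on the Ensembl release 115 annotation of WBcel235, the assembly that ce11 also names, with sequence, tRNA isotypes and small RNA names from its RefSeq copy. A summit was a promoter if it lay 1 to 1000 bp upstream of an annotated transcript start of a protein-coding gene. Otherwise it was placed in the first of these classes that applied: 5' UTR, coding exon, 3' UTR, intron, non-coding RNA exon, intergenic. Many annotated transcript starts in C. elegans are trans-splice sites, so the true start can lie further upstream. A summit was assigned to the protein-coding gene with the nearest transcript start, if within 5000 bp. Distances to genes of small RNAs were counted from the summit to the nearest base of the gene, and 100 bp was the limit.

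Shares of peaks are given with exact (Clopper-Pearson) 95% intervals. Peaks and background regions were compared with two-sided Fisher's exact tests, with odds ratios and their exact conditional 95% intervals, and Benjamini-Hochberg adjustment within each family of tests. Regions are not biological replicates: these intervals and p-values describe 1 set of regions, and neighbouring regions are not independent. The replicates enter through the overlap of their lists and through repeats on the 741 top regions of each replicate alone. These repeats covered the promoter, X chromosome, tRNA gene, snoRNA gene, octamer and GAGA repeat shares. They also covered the distance and strength tests of the octamer, the gene lists and the 8-mers. Tests of the other motifs, other annotation classes and single-copy tRNA genes were not repeated in this way. The position of the octamer was tested with 100000 random placements. The sequence windows reached 100 bp to each side of the summit. All 32896 8-mers, each joined with its reverse complement, were tested for presence in those windows.

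Before the data were examined, the tests, the 7 motifs, 22 gene lists, the alternatives and the rule for named genes were fixed. That rule took the genes assigned to the 15 IDR peaks of highest signal, ceh-6, aqp-8 and unc-119 whatever their values, and up to 4 members of each list with the strongest assigned peak. Of the symbols in the lists, 5 matched no protein-coding gene of the annotation. The alternatives fixed beforehand were other peak thresholds, other rules of overlap, other backgrounds (weaker regions, random positions, flanks, matched GC content), other windows and promoter lengths, other rules of gene assignment, and each replicate alone. The tests of genes of small RNAs, of families of such genes and of the GAGA repeat under other settings were chosen after the data were seen. The test of the B box, a sequence inside tRNA genes, was not among those fixed beforehand either. Regions on the mitochondrial genome were kept except in the comparison of chromosomes, and leaving them out was an added alternative.

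The searches were tested on simulated data. With no 8-mer changed, 0 of 32896 8-mers passed. The simulated peaks were drawn from background regions, so this did not test differences in base composition between peaks and background. When 20 8-mers were planted at 2 times their background share, 25% of them were recovered, and at 4 times 100% were. Of 100 random gene sets of the size found here, 1 gave at least 1 list past the threshold. For lists of 15 to 60 genes, 65.7% were called when 20% of the members were made to carry a peak, 100% when 40% were, and 0% when 10% were, so weak enrichments of short lists would be missed. The distance test gave p under 0.05 in 6 of 100 sets of random genome positions. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.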

Results

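CEH-6 was pulled down through its eGFP tag from late embryos of C. elegans in 2 biological replicates. CEH-6 is known from earlier work as a factor of the excretory canal cell, of rectal epithelial cells and of some neurons. The deposited IDR set held 741 peaks with a median width of 410 bp and signal values from 105.7 to 1484, with a median of 151. The relaxed lists of replicates 1 and 2 held 30000 regions each, with median signals of 19.7 and 26.2. These signals are the authors' own and are compared only within a list. Read depth is unknown.

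The first comparison asked how far the replicates share the peaks. Of the 741 IDR peaks, 573 (77.3%, exact 95% interval 74.1 to 80.3%) had their summit in one of the 741 top regions of replicate 1, and 629 (84.9%, 82.1 to 87.4%) in one of the 741 top regions of replicate 2. Both replicates held 483 of the peaks (65.2%, 61.6 to 68.6%) among their top regions, and 22 (2.97%, 1.87 to 4.46%) were in neither set. In the full relaxed lists, 727 peaks were covered by a region of each replicate. The IDR peaks are the top 741 regions of the pooled list, so weak peaks lie near the limit of 741 regions in each replicate by construction. That list was called on the reads of both replicates, which can raise the overlap of each replicate with the peaks. Compared directly, 480 of the 741 top regions of replicate 1 (64.8%, 61.2 to 68.2%) had their summit in a top region of replicate 2. Of the 185 strongest peaks, 178 (96.2%, 92.4 to 98.5%) were among the top regions of both replicates, against 22 of the 185 weakest (11.9%, 7.60 to 17.4%). Peaks within 100 bp of a tRNA gene were shared by both top sets in 162 of 196 cases (82.7%, 76.6 to 87.7%), and the other nuclear peaks in 308 of 522 (59.0%, 54.6 to 63.3%). These 2 classes were not matched on strength. A tRNA gene was near 43.2% of the 185 strongest peaks and 26.5% of all peaks.

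The strongest peaks lay at genes of small RNAs and on the mitochondrial genome. Among the 15 peaks of highest signal, 7 had a snoRNA gene within 100 bp of the summit, 1 a tRNA gene, 4 were mitochondrial and 3 had none of these. The strongest (chromosome V, 12303421 to 12303829, signal 1484) lay at the snoRNA genes C51F7.3 and C51F7.4. It ranked 1 in replicate 1 and 2 in replicate 2, and the nearest protein-coding transcript start, 1097 bp away, was that of F55C5.17. The next nuclear peak (II, 11960642 to 11961040, signal 1355) lay at the snoRNA gene W03C9.9, with the nearest coding start that of W03C9.1, and ranked 2 and 3 in the replicates. Peaks assigned to sre-23 (I, 8259385 to 8259745, signal 1164) and str-56 (V, 15873761 to 15874160, signal 1007), both of chemoreceptor families, lay at the snoRNA genes ZK265.10 and T06C12.16. In an intron of cutl-18, a cuticlin-like gene, a peak (V, 11314024 to 11314428, signal 1122) lay at the snoRNA gene T03F7.8. Another intronic peak (V, 8500397 to 8500731, signal 847) had no coding start within 5000 bp and lay at the snoRNA gene ZK994.7, and the peak assigned to T02E1.2 (I, 8224255 to 8224583, signal 702) lay at T02E1.9. The peak assigned to C04A11.5 (X, 13665416 to 13665783, signal 916) lay at a tRNA gene. The remaining peaks of the 15 were assigned to hrg-5, a haem-responsive gene (IV, 11025910 to 11026402, signal 900, within 100 bp of the miRNA gene mir-51), K12H4.5 (III, 8043818 to 8044119, signal 790) and T13C5.6 (X, 6207678 to 6208072, signal 724). The last 2 were in promoters, 517 and 190 bp upstream of the transcript start.

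Peaks were concentrated in promoters of protein-coding genes and rare in coding exons. Of the 741 summits, 338 (45.6%, 41.98 to 49.3%) were in promoters, against 24.3% of the 29094 background regions, an odds ratio of 2.62 (2.25 to 3.04, Fisher's exact test, p = 1.19e-35). Coding exons held 16 peaks (2.16%, 1.24 to 3.48%) and 26.98% of background regions (odds ratio 0.0597, adjusted exact p = 7.84e-74). Exons of non-coding RNA genes held 74 peaks (9.99%, 7.92 to 12.4%) and 1.33% of background regions (odds ratio 8.23, adjusted exact p = 2.31e-37). Intergenic summits were fewer than in the background (13.2% against 18.8%, adjusted exact p = 0.000138), and so were those in 3' UTRs (0.270% against 1.76%, adjusted exact p = 0.000621). Introns (24.97% against 25.5%, adjusted exact p = 0.765) and 5' UTRs (0.675% against 1.34%, adjusted exact p = 0.161) did not pass the test. Promoters and introns came before non-coding RNA exons in the order of classes. Peaks at genes of small RNAs inside introns, such as the strongest peak, therefore counted as intronic. Once regions within 100 bp of a tRNA, snoRNA, snRNA or rRNA gene and on the mitochondrial genome were left out, the promoter share was 59.6% of 460 peaks against 24.2%, with an odds ratio of 4.61.

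**Figure D1:**
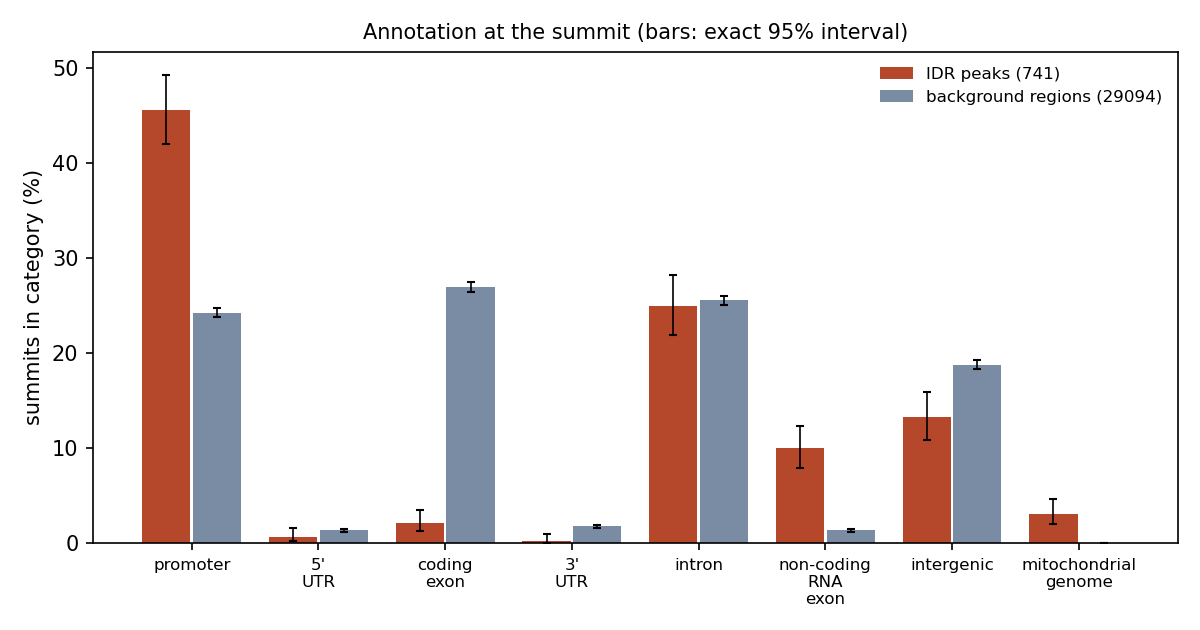
Share of summits (vertical axis, percent) in each annotation class for the 741 IDR peaks and the 29094 background regions, with exact 95% intervals as error bars. Promoters held 45.6% of peaks and 24.3% of background regions, and coding exons 2.16% and 26.98%.

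Genes of tRNAs and snoRNAs, small RNAs that act in translation and in the modification of rRNA, had the highest odds ratios among the classes of RNA gene compared. A nuclear tRNA gene lay within 100 bp of 196 of the 741 summits (26.5%, 23.3 to 29.8%) and of 0.588% of background regions, an odds ratio of 60.8 (48.4 to 76.4, Fisher's exact test, adjusted p = 4.83e-219). The size of this ratio moved with the regions compared, to 105 for the top 370 peaks, 145 against the weaker part of the background and 249 against random genome positions. A snoRNA gene was as close to 53 summits (7.15%, 5.40 to 9.25%) and to 0.258% of background regions (odds ratio 29.8, 20.4 to 43.3, adjusted exact p = 2.65e-50). That ratio was 60.5 for the top 370 peaks and 63.96 against random positions. For snRNA genes the numbers were 9 peaks (1.21%) and 0.120% (odds ratio 10.2, adjusted exact p = 2.51e-06). Neither a peak nor a background region was near a nuclear rRNA gene, so that class could not be compared. The broad annotation class of other non-coding RNAs was near more peaks, 237 (31.98%), and near 5.74% of background regions (odds ratio 7.72). Of those peaks, 122 had no tRNA gene within 100 bp. Genes of miRNAs (3 peaks), lincRNAs (4 peaks) and piRNAs (1 peak) did not pass the test, and pseudogenes were less often near a peak than near a background region (6 peaks, 0.810% against 2.47%, adjusted exact p = 0.00278).

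Counted by gene, 199 of the 612 nuclear tRNA genes (32.5%, 28.8 to 36.4%) had an IDR peak within 100 bp. The genes were of 21 isotypes, and none of the 20 with at least 10 genes differed from the rest (lowest adjusted exact p = 0.682, for Cys with 8 of 13 genes). Peaks were near 31 of the 140 tRNA genes whose sequence occurs once in the nuclear genome (22.1%, 15.6 to 29.9%) and near 168 of the 472 with identical copies (35.6%, 31.3 to 40.1%), an odds ratio of 0.515 (0.320 to 0.812, Fisher's exact test, p = 0.00283). Most summits lay upstream of the middle of the gene. Relative to the middle of the gene and on its strand, the median position of the 198 summits within 250 bp was -26 bp, with an interquartile range from -41.4 to 0.750 bp. The share of regions near a tRNA gene was 43.2% in the 185 strongest peaks, 33.5% in the next 185, 14.6% and 14.5% in the following sets of 185 and 186, and 4.35% in the regions ranked 742 to 1500 of the pooled list. For snoRNA genes the shares in the same sets of peaks were 22.7%, 4.32%, 1.62% and 0%. The top 741 regions of each replicate alone gave tRNA shares of 24.97% (21.9 to 28.2%) and 24.8% (21.8 to 28.1%).

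**Figure D2:**
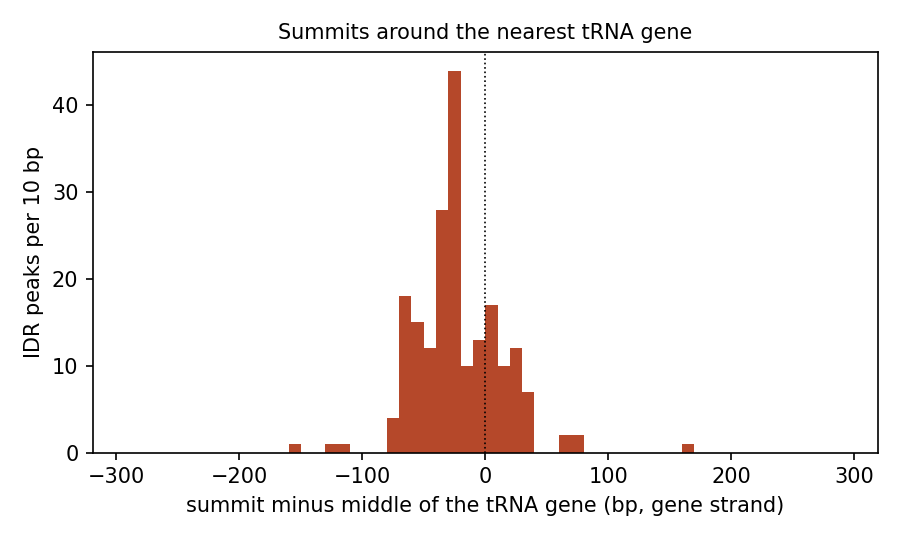
Distance from the middle of the nearest tRNA gene to the peak summit (horizontal axis, bp, negative values upstream on the gene's strand) for the 198 IDR peaks within 250 bp of a tRNA gene, counted in bins of 10 bp (vertical axis). The median position is -26 bp.

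The X chromosome carried 200 of the 718 nuclear peaks (27.9%) and 16.96% of background regions, an odds ratio of 1.89 (1.59 to 2.24, Fisher's exact test, p = 7.52e-13). X had 11.3 peaks per Mb, and the autosomes from 4.30 on V to 8.71 on III. X also carried 276 of the 612 nuclear tRNA genes (45.1%). Peaks were near 31.9% of the tRNA genes on X (88 of 276) and 33.04% of those on the autosomes (111 of 336), a difference within the error (odds ratio 0.949, 0.665 to 1.35, exact p = 0.795). Without regions within 100 bp of a tRNA gene, 21.8% of peaks and 16.8% of background regions were on X, and the odds ratio was 1.38 (1.11 to 1.71, exact p = 0.00319). Without regions near a tRNA, snoRNA, snRNA or rRNA gene it was 1.61 (1.28 to 2.00, exact p = 3.30e-05), with 24.6% of peaks and 16.9% of background regions on X.

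The POU octamer ATGCAAAT, the textbook site of POU homeodomain proteins, showed no detectable excess at the peaks over the background. It lay within 100 bp of 15 of 741 summits (2.02%, 1.14 to 3.32%) and of 1.83% of background regions, an odds ratio of 1.11 (0.612 to 1.86, Fisher's exact test, p = 0.676). The interval leaves room for a 1.86 times higher odds and for lower odds. In the 4 sets of peaks ordered by strength the octamer shares were 1.08%, 1.08%, 4.32% and 1.61%, and no difference was detectable between the strongest and weakest 185 peaks, with 2 and 3 octamers (odds ratio 0.663, 0.0548 to 5.86, exact p = 1). With so few octamers the ratio varied. It was 0.162 without replicate 1 (1 and 6 octamers), 0.246 without replicate 2 (1 and 4) and 0.357 for the top against the bottom 370 peaks (4 and 11, 0.0822 to 1.22, exact p = 0.115). No gathering of octamers at the summit was detectable. Where one lay within 500 bp (57 peaks), its mean distance was 234 ± 154 bp (SD over 57 peaks), against 246 bp for uniform placement (permutation p = 0.516). When 1 mismatch was allowed the share was lower in peaks than in background regions (22.7% against 27.8%, odds ratio 0.763, exact p = 0.00206). Peaks were richer in GC than background regions, with means of 47.98% and 42.1% over the windows (SD over regions 7.24 and 7.06). The comparison with 1 mismatch was not matched on GC content.

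**Figure D3:**
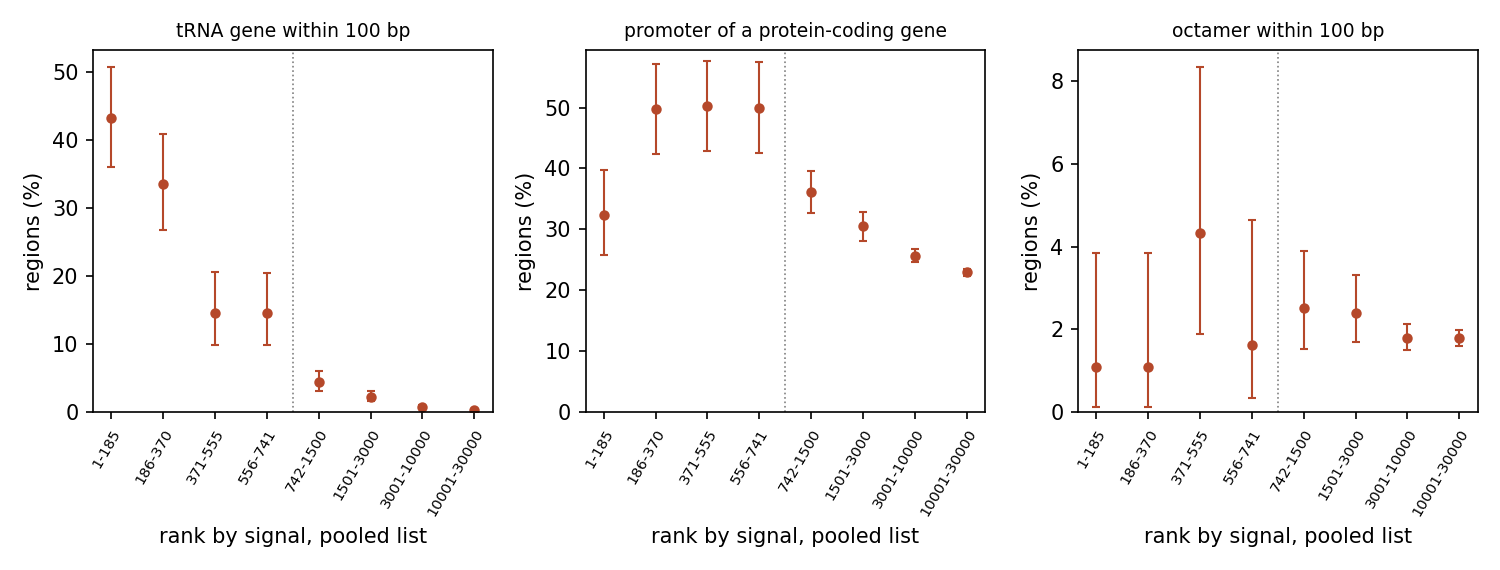
Share of regions (vertical axes, percent, with exact 95% intervals) with a tRNA gene within 100 bp, in a promoter, or with an octamer within 100 bp, by rank of signal in the pooled list (horizontal axes). Regions left of the dotted line are the 741 IDR peaks. The tRNA share falls from 43.2% in the strongest 185 regions to 0.315% in the weakest set, while the octamer share stays between 1.08% and 4.32%.

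Of the other motifs fixed beforehand, a GAGA repeat (GAGAGAGA) was more frequent at peaks, and the GATA site and the SOX half-site were less frequent. The GAGA repeat lay at 60 peaks (8.10%, 6.24 to 10.3%) and 3.52% of background regions, an odds ratio of 2.42 (1.81 to 3.18, adjusted exact p = 7.77e-08). Against random genome positions, of which 1.40% had the repeat, the odds ratio was 6.23. For the top 370 peaks it was 1.65 (1.00 to 2.58, unadjusted exact p = 0.0327), with the repeat at 5.68% of them. The GATA site TGATAAG was at 7 peaks (0.945% against 2.82%, odds ratio 0.328, adjusted exact p = 0.00314) and the SOX half-site ACAATG at 58 (7.83% against 11.2%, odds ratio 0.675, adjusted exact p = 0.00846). Both sites hold more A and T than G and C, and peaks were richer in GC than the background. None of these other motifs was compared with background of matched GC content, so base composition was not separated from the sites. The palindromic POU site (5 peaks, odds ratio 0.656, adjusted exact p = 0.640), the SOX-POU composite (19 peaks, odds ratio 0.748, adjusted exact p = 0.449) and the E-box CAGCTG (43 peaks, odds ratio 1.05, adjusted exact p = 0.744) did not pass.

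The search over all 8-mers was led by sequences found in tRNA genes. At an adjusted p under 0.05, 1674 of 32896 8-mers were more frequent at peaks and 260 less frequent. The first was GGGTTCGA, part of the B box that lies inside tRNA genes, at 89 peaks (12.0%) and 0.612% of background regions (odds ratio 22.2, adjusted exact p = 1.47e-70). It was followed by ATCGAACC (8.10% against 0.516%) and CTGAGCTA (7.83% against 0.522%). The octamer was not among the 8-mers that passed (adjusted exact p = 0.989), and 138 of the 840 8-mers with its base composition on either strand had a higher odds ratio. Without regions near genes of small RNAs and on the mitochondrial genome, 753 8-mers were more frequent at the 460 remaining peaks. These 753 were led by the dinucleotide repeat CACACACA (15% of peaks against 3.03%, adjusted exact p = 3.55e-22) and the same repeat read as ACACACAC (14.6% against 2.89%). They were followed by ACACTCAC (7.83% against 0.788%) and CGCACACA (7.83% against 0.972%). The octamer did not pass there either (odds ratio 1.68, adjusted exact p = 0.588), and 33 of the 840 8-mers of its composition had a higher odds ratio. With the top 370 peaks alone the count for the full set was 972. The 8-mer search was not matched on GC content.

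The gene encoding CEH-6 carried 2 IDR peaks. The transgene holds ceh-6 sequence too, so reads at these peaks need not come from the native gene. The stronger (I, 8501778 to 8502187, signal 183, rank 273) lay in an intron of ceh-6, 621 bp downstream of its nearest transcript start, and ranked 198 in replicate 1 and 391 in replicate 2. The other (I, 8499783 to 8500192, signal 118.98, rank 570) lay in a coding exon, 2616 bp downstream, and ranked 8910 in replicate 1 and 348 in replicate 2. The aquaporin gene aqp-8, which is expressed in the excretory canal, and the marker gene unc-119 had no assigned IDR peak. Within 2000 bp of these genes the best region of the pooled list ranked 7954 (aqp-8, signal 50.7) and 11972 (unc-119, signal 44.2).

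In all, 675 of the 741 peaks were assigned to 620 of the 19973 protein-coding genes (3.104%). Among the 22 gene lists, the chemoreceptor families differed from all other genes, with fewer peaks. Of 1309 chemoreceptor genes, 8 had an assigned peak (0.611%, 0.264 to 1.201%) against 3.28% of other genes, an odds ratio of 0.181 (Fisher's exact test, adjusted p = 6.33e-09). The strongest were the peaks of sre-23 and str-56 given above, srd-43 (X, 13306923 to 13307188, signal 491), which lay at a tRNA gene, and srt-52 (V, 53390 to 53603, signal 310). Without regions near genes of small RNAs, 3 chemoreceptor genes had a peak (adjusted exact p = 3.15e-07). No list had more peaks than other genes at an adjusted p under 0.05. At an unadjusted p under 0.05 the ribosomal protein list and the SOX and TCF list were above the other genes.

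Ribosomal protein genes had a peak in 6 of 81 cases (7.41%, 2.77 to 15.4%, against 3.09% of other genes, exact p = 0.0400, adjusted 0.257). All 6 kept it when regions near genes of small RNAs were left out. The strongest were at the promoters of rpl-3 (III, 3867463 to 3867695, signal 365), rpl-35 (III, 7854480 to 7854889, signal 236), rpl-15 (IV, 654742 to 655151, signal 224) and rps-28 (IV, 1659037 to 1659446, signal 179), between 270 and 449 bp upstream of the transcript start. When every gene with a transcript start within 1000 bp was counted, this list passed the adjusted threshold. It also passed, together with the cell cycle list, on the top regions of replicate 1 alone, which left 3 lists past the threshold. Of the 10 genes found of the SOX and TCF list, 2 had a peak (adjusted exact p = 0.257). One was hmg-1.1 (II, 14250237 to 14250646, signal 191, promoter), an HMG box gene whose symbol is not that of a SOX or TCF factor. The other was sox-2 (X, 7457577 to 7457986, signal 121), a SOX factor that acts with CEH-6 in the conversion of the Y cell to the PDA neuron. The sox-2 summit lay in an exon of a non-coding RNA gene, 1970 bp downstream of the nearest sox-2 transcript start and beyond the 3' end of sox-2.

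The lists nearest to the known sites of CEH-6 function did not pass. Their odds ratios were 3.48 for the excretory canal, 3.29 for the rectal epithelium and Y-to-PDA list and 0 for the V-ATPase. In the simulations 0% of lists of 15 to 60 genes were called when 10% of the members carried a peak. An enrichment of the size seen in the first pair of lists could therefore have been missed. Of 30 genes of the excretory canal, 3 had a peak (10%, 2.11 to 26.5%, adjusted exact p = 0.257), the sodium/proton exchanger nhx-9 (IV, 11928370 to 11928779, signal 140), the Prospero homologue pros-1 (III, 8069258 to 8069667, signal 126) and the aquaporin aqp-2 (II, 9258055 to 9258464, signal 115.3). The summits of nhx-9 and pros-1 lay within 100 bp of a tRNA gene, and without such regions 1 of the 30 genes had a peak. That gene was aqp-2, whose summit was intergenic. It lay beyond the 3' end of aqp-2, 3719 bp downstream of the transcript start. Of 21 genes of the rectal epithelium and the Y-to-PDA conversion, ceh-6 and sox-2 had a peak (9.52%, 1.17 to 30.4%, adjusted exact p = 0.336). None of 21 V-ATPase genes did (adjusted exact p = 1, upper limit 16.1%). Of 100 homeobox genes, 4 had a peak, ceh-6, ceh-38 (II, 6951390 to 6951799, signal 147, promoter), pros-1 and unc-62, a Meis homologue (V, 4499223 to 4499632, signal 106, promoter).

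Lists of other tissues and processes gave small counts. The glial list had 2 of 17 genes (itx-1, signal 114.8, and pros-1), the pan-neuronal list 1 of 29 (unc-33, signal 129), the proneural bHLH list 1 of 15 (lin-32, X, 2227002 to 2227411, signal 271, at a tRNA gene), the muscle list 1 of 34 (unc-112, signal 118) and the hypodermis and seam list 2 of 44 (ajm-1, signal 138, and egl-18, signal 123). No peak was assigned to the 31 intestinal, 27 pharyngeal and 19 T-box genes. The Wnt pathway had 3 of 30 genes (vang-1, X, 2885341 to 2885750, signal 168, lit-1, signal 109, and lin-17, signal 106), the Notch pathway 1 of 26 (sel-8, signal 138), and the cell cycle list 3 of 33. The last were the cyclin E gene cye-1 (I, 6781656 to 6781958, signal 559, at a tRNA gene), mdf-2 (signal 135, also at a tRNA gene) and the inhibitor gene cki-1 (signal 109). Histones had 3 of 72 genes, with peaks 184, 160 and 118 bp upstream of his-67 (signal 213), his-61 (signal 114) and his-60 (signal 106). Collagens had 6 of 156 genes. The 4 strongest, col-181 (signal 615), col-99 (signal 501), col-94 (signal 489) and col-85 (signal 433), lay at a tRNA gene or, for col-94, at an snRNA gene. Nuclear hormone receptors had 3 of 269 genes (nhr-255, signal 325, nhr-41, signal 218, and nhr-175, signal 156), of which the first pair lay at tRNA genes. The list of insulin-like and FMRFamide peptide genes had peaks in 4 of 140 cases (nlp-76, signal 543, ins-13, signal 196, flp-23, signal 175, and ins-39, signal 109). The symbol of nlp-76 is not that of an insulin-like or FMRFamide peptide gene. The peaks of nlp-76 and flp-23 lay at tRNA genes and that of ins-13 at the SL2 RNA gene sls-2.2. The lowest adjusted exact p in these lists of other tissues and processes was 0.257.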

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

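Regions on the mitochondrial genome lie outside the nuclear chromosomes that the study's factor is known to act on, and the comparison of chromosomes did not use them. Of the 741 IDR peaks, 23 were mitochondrial (3.104%, exact 95% interval 1.98 to 4.62%). They included all 23 mitochondrial regions of the pooled list, which covered 53.5% of the 13794 bp. Of these, 18 were among the 185 strongest peaks, and the strongest ranked 2. Replicates 1 and 2 held 23 and 18 mitochondrial regions among their own 741 top regions. Of the 23 mitochondrial peaks, 13 (56.5%, 34.5 to 76.8%) had their summit in a top region of both replicates.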

How the results depend on the processing

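The region exclusions and the alternatives of the tRNA, snoRNA and GAGA shares were chosen after seeing the data. Of 86 alternative values, 68 kept their direction and their side of the threshold, or stayed within the interval or within 1.5 times a count. Among them were all those of the promoter, X chromosome, tRNA gene, snoRNA gene and GAGA repeat shares, although the tRNA odds ratio ranged from 50.4 to 249, the snoRNA one from 29.2 to 63.96 and the GAGA one from 1.65 to 6.23. The overlap with replicates 1 and 2 rose to 97.03% and 98.1% for the top 370 peaks and fell to 70.4% and 80.3% with 50% reciprocal overlap. Without regions near a tRNA gene it was 73.03% and 82.02%, and with summits within 100 bp it was 73.3% for replicate 1. The octamer odds ratio fell below 1 for the top 370 peaks (0.586), with windows of 50 bp (0.600) and 250 bp (0.916), and with up to 1 mismatch (0.763), and ranged from 0.957 to 1.15 without replicate 1 or 2. The octamer odds ratio was higher, 1.39, against flanking windows and 1.40 against background of matched GC content. It was 1.42 without regions near a tRNA gene, and 1.68 without regions near genes of small RNAs and on the mitochondrial genome. Among all these values only that with 1 mismatch passed the threshold. The mean octamer distance was 285 bp for the top 370 peaks, above the 243 bp of uniform placement (permutation p = 0.144). For the top 370 peaks the octamer share by strength gave no value, as neither set of 92 peaks had an octamer, and its other odds ratios ranged from 0.162 to 0.357 against 0.663. Gene lists past the threshold numbered 2 with every transcript start within 1000 bp, and 1 to 3 without replicate 1 or 2. The 8-mers numbered 972 for the top 370 peaks, 799 without regions near a tRNA gene and 753 without regions near genes of small RNAs and on the mitochondrial genome. The cause was not tested, and the top 370 peaks hold fewer regions by construction. No paired analysis was possible because there is one group. Unknown depth limits every comparison of the replicates.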

Other observations

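The tests of small RNA families, the use of the ribosomal protein list to weigh the tRNA peaks, and the odds ratios without regions near genes of small RNAs were chosen only after the data were seen. The B box test below was not among the tests fixed beforehand either. Some other families of genes known to be transcribed by RNA polymerase III carried peaks as well, but 0 of 16 genes of 5S rRNA did. The spliced leader genes given below are not counted among those families, and 3 of 18 SL2 genes had a peak. Among genes of the signal recognition particle RNA, 3 of 5 had an IDR peak within 100 bp (60%, exact 95% interval 14.7 to 94.7%): srpr-2.2 (III, 5031410 to 5031708, peak signal 317), srpr-2.1 (III, 5211220 to 5211518, peak signal 199) and srpr-1.2 (III, 4369468 to 4369766, peak signal 172). Both rpr-1 (I, 13463955 to 13464207, peak signal 417), the RNA of RNase P, and mrpr-1 (II, 7200233 to 7200418, peak signal 349), the RNA of RNase MRP, had one. Of 22 snRNA genes with the sequence ACAGAGA, an invariant box of U6, 4 had a peak (18.2%, 5.19 to 40.3%), the strongest being W05B2.8 (III, 10989679 to 10989780, peak signal 489). Of the 77 other snRNA genes outside the spliced leader families 1 had a peak (1.299%, 0.0329 to 7.02%). Among spliced leader genes, 3 of 18 SL2 genes and 0 of 12 SL1 genes had a peak, and 0 of 16 genes of 5S rRNA did (upper limit 20.6%), although no background region lay near a nuclear rRNA gene either. The last 2 families are repeated, and how the authors treated reads that map to several places is not given in the sources used here. The differences between these families were not tested.

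A peak also lay at each of mir-51 (IV, 11026013 to 11026112, peak signal 900, rank 10) and mir-52 (IV, 14034008 to 14034107, peak signal 297), members of the mir-51 family. The third miRNA gene with a peak was mir-5549 (peak signal 109). Around ceh-6, the pooled list held 8 regions within 20000 bp of the gene, against 13.3 expected from the genome mean, around unc-119 it held 19 against 13.8, and around aqp-8, which is not named in the transgene, 19 against 12.8.

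Peaks at tRNA genes were weighed first. Of the 140 single-copy genes 22.1% had a peak, more than 8.90%, which is the share in genes with copies divided by 4. This argues against reads shared between identical tRNA gene copies as the only source. Shared reads are not excluded, because single-copy here means only that the exact sequence occurs once. Genes that differ slightly can still share reads. A single-copy gene can also lie beside a gene with copies, as W09G10.t3 does beside W09G10.t2, and both had a peak within 100 bp. The treatment of reads that map to several places is unknown. The lower share of single-copy genes leaves room for a part of the effect. A single aberrant replicate is excluded, as the lower of both replicates' shares was 24.8%. A pull-down at highly transcribed genes in general may contribute and stays open: 7.41% of ribosomal protein genes had a peak, and the interval of 2.77 to 15.4% includes the 3.09% of other genes. No mock or untagged immunoprecipitation was analysed here, and no biological explanation was tested.

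The excess of peaks on X was weighed against the location of tRNA genes. That location cannot account for all of it, since the odds ratio without regions near a tRNA gene was 1.38 and its interval stayed above 1. It was 1.89 with them and 1.61 (1.28 to 2.00) without regions near a tRNA, snoRNA, snRNA or rRNA gene. Of the 200 peaks on X, 86 lay within 100 bp of a tRNA gene. The share of nuclear peaks on X was 27.9% with such regions and 21.8% without them. By count, peaks near tRNA genes thus made up a part of the excess. The differences between the odds ratios were not tested. No biological explanation was tested, as the design has 1 group.

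Among possible sources of the missing octamer excess, dilution and base composition were weighed, and others were not tested. Octamer sites could be diluted by peaks at genes of small RNAs and on the mitochondrial genome. The GC content of the peaks could also play a part. Without those regions the odds ratio was 1.68 (0.904 to 2.87), and against background regions of matched GC content it was 1.40 (0.751 to 2.43). In the set without those regions 33 of the 840 8-mers of the same composition had a higher odds ratio than the octamer, against 138 in the full set. Both intervals of the odds ratio include 1 and reach beyond 2, so neither explanation was settled. With 14 octamers among 460 peaks the number of sites limits the test.

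A hypothesis was that peaks without a tRNA, snoRNA, snRNA or rRNA gene within 100 bp mark other genes with an internal B box. The box GGTTCGANNCC with up to 1 mismatch lay within 100 bp of 21 of 460 such peaks (4.57%, 2.85 to 6.89%) and of 2.40% of background regions without such genes, an odds ratio of 1.95 (1.19 to 3.04, Fisher's exact test, p = 0.00559). Of these peaks, 9 lay at a miRNA gene or at the genes of the signal recognition particle, RNase P or RNase MRP RNA described above. Without such regions, as tested later, the box was at 20 of 451 peaks (odds ratio 1.89, 1.14 to 2.98, exact p = 0.0121). Unannotated or other genes with a B box could lie at a few of these peaks, and 439 of the 460 peaks had no such box. The background was not matched on GC content here. All IDR peaks together averaged 47.98% GC and the background regions 42.1%. The test therefore cannot tell such genes from a difference in base composition.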
